A study of Mus musculus with 25 samples.

How the data were processed

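RNA was measured by sequencing in 25 mouse libraries, each made from 200 sorted cells. The sorted cells were 4 macrophage populations of white adipose tissue (eWAT in the titles) and a monocyte population of blood, from C57BL6 mice on a control diet (CD, 10% fat) or a high fat diet (HFD, 45% fat), per the labels. The deposited table holds raw read counts for 24537 RefSeq gene models, of which 20712 are protein-coding and 394 have several copies in the genome. Per the submitters' processing notes, reads were aligned with STAR 2.5.3a to the mm10 build and counted with HOMER. The deposited table also gives each gene model's length in bases and its number of copies, which entered no test. Strand, duplicate removal, the treatment of reads with several matches and the annotation version are not stated in the labels or the file headers. Near-identical genes, such as Cd209f and Cd209g, Klrb1a and Klrb1b, the Ly6 genes, the haemoglobin genes and the class II H2 genes, are therefore uncertain, because reads could have been split or dropped between them. Overlapping and antisense genes are uncertain for the same reason. Coordinates are given as in the file, on mm10. The table lists no mitochondrially encoded genes.

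Libraries were grouped by population and diet into 10 groups. Each adipose group held 2 libraries, the control monocytes 6 and the HFD monocytes 3. The control libraries carry the titles CD or CD-CD, and all adipose control libraries are titled CD-CD, so in adipose tissue the diet comparison is also a comparison of title series. The labels do not say whether libraries with the same number come from the same animal, how many animals stand behind a library, or how long the diets lasted. P-values may therefore measure technical as well as animal-to-animal spread. Adipose tissue was digested with collagenase in the presence of flavopiridol, an inhibitor of transcription, whereas the labels describe no digestion of blood. Tissue, gate and handling are thus confounded in the comparison of monocytes with adipose macrophages.

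Total counts ranged from 3.75 to 9.34 M per library, and the most abundant gene took 0.159% to 0.407% of a library's counts. A floor of 3 counts corresponded to 0.321 to 0.799 CPM (counts scaled by library total). Floors and counts of 0 cover counting error only, since the reads carry no molecular identifiers. CPM values were computed from the deposited counts with library sizes scaled by TMM factors (0.89 to 1.15) and are given as mean ± SD over the n libraries of a group.

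Differences were tested with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood F test (estimateDisp, robust glmQLFit, glmQLFTest) after filterByExpr by group, with Benjamini-Hochberg adjustment and a threshold of adjusted p 0.05. All 25 libraries entered 1 fit of 10 group means with 16961 genes, 15 residual degrees of freedom and a common biological coefficient of variation of 0.749 (0.744 in the adipose libraries alone and 0.677 in the monocytes alone). All adjusted p-values of genes in the text come from this test unless another tool is named. Contrasts compared the mean of the 8 adipose groups with the mean of the 2 monocyte groups, Tim4+ with Tim4- populations, pop1 with pop2, pop3 with pop4, HFD with CD within each population, and the diet effect of Tim4+ with that of Tim4- populations. Diet was also tested on counts summed over the 4 adipose populations per title number (2 CD and 2 HFD sums, 17806 genes), and the CD and CD-CD title series were compared in monocytes (11308 genes). Standard errors (SE) of log2 differences are given in parentheses. A fitted log2 value against a group below the floor depends on the prior count, so levels are given beside it or in its place (for the difference of diet effects, the genes concerned are named), and no fold is given where every library of a group had 0 counts (2 fitted differences of diet effects with such a group are given as fitted values only).

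A total of 30 gene lists were fixed before the data were examined: sort markers, resident macrophage, antigen presentation, dendritic cell, lipid-associated macrophage, growth factors, inflammatory cytokines, interferon-stimulated, proliferation, classical monocyte, non-classical monocyte, sterol and fatty acid synthesis, oxidative phosphorylation, lysosome, iron and heme handling, complement and scavenging, immediate early and heat shock, peritoneal macrophage, T cell, B cell, NK cell, neutrophil, eosinophil and mast cell, adipocyte, stromal progenitor, endothelial, mesothelial, red cell, platelet and sex chromosome check. Of their 414 genes, 410 were in the table. Lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over the lists of a comparison. Counts of list members past the threshold are given over all genes tested and adjusted over the list alone.

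The genes named in the text follow a rule also fixed before the data were examined: up to 8 genes each way with the largest fold among those past the threshold whose libraries do not overlap between the sides and whose higher side averaged at least 20 CPM (genes with Gm, Rik or LOC names, pseudogenes and small RNAs aside), members of the lists described, and in every comparison the genes of the sort gates and Pdgfc. In such a gene every library of the higher side lay above every library of the lower side. Where no gene passed, the 4 with the smallest p were given as values. For the summed adipose libraries and the difference of diet effects, the condition on overlap was not applied. Some genes that met the rule are not reported here.

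Alternatives were the size factors of DESeq2 1.42.0 and upper-quartile factors, no filter and a filter of 50 counts in at least 4 libraries, the DESeq2 Wald test, limma-voom with quality weights, fits of only the compared groups, the title number as a block, and each library left out in turn. Added after the data were seen were contrasts of single diets within the fit of all 25 libraries. Fits of the 16 adipose libraries and without both pop2 HFD libraries were added then as well. So was a fit with a background covariate, the log2 CPM in 1456 olfactory and vomeronasal receptor genes. The tests were tried on simulated counts with 100 genes changed 4-fold and 100 changed 16-fold: edgeR found 66 and 93 of them, with 7 false calls, for monocytes against adipose macrophages (15374 genes). It found 51 and 95, with 2 false calls, for Tim4 (15404 genes), 44 and 79, with 4 false calls, for pop3 against pop4 (15385 genes), and 14 and 50, with 2 false calls, for diet in pop1 (15433 genes). For diet in monocytes it found 41 and 73, with 1 false call (15392 genes). For the difference of diet effects the changes were placed in Tim4+ HFD and Tim4- CD groups, which doubles the log2 difference, and it found 63 and 91, with 12 false calls (15435 genes). DESeq2 made 61 to 106 false calls in these 6 simulations. Apart from the changed genes, which were taken above a minimum level, the simulated libraries shared a common mean per gene. Their spread was the one estimated from the data, equal in all groups. The simulations therefore do not test whether the real groups share an equal spread, on which the diet calls rest. No library or value column was left out.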

Results

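The data are read counts of 25 libraries made from sorted myeloid cells of C57BL6 mice. In the adipose tissue 4 macrophage populations were sorted: pop1 (Tim4+, MHCII low), pop2 (Tim4+, MHCII high), pop3 (Tim4-, CD11c-, MHCII high) and pop4 (Tim4-, CD11c+, MHCII+). Blood monocytes were sorted on CD115 and Ly6C. Each adipose population had 2 libraries per diet, and monocytes had 6 libraries on the control diet (CD) and 3 on the high fat diet (HFD). Total counts (in M) were 5.11 to 6.49 in pop1 CD, 5.59 to 6.63 in pop1 HFD, 4.73 to 5.86 in pop2 CD, 3.75 to 4.48 in pop2 HFD and 5.07 to 5.57 in pop3 CD. They were 7.75 to 8.52 in pop3 HFD, 7.06 to 7.81 in pop4 CD, 7.98 to 8.24 in pop4 HFD, 8.41 to 9.34 in monocytes CD and 6.5 to 9.0 in monocytes HFD. Log2 CPM of the 2 libraries of an adipose group correlated across genes at 0.88 to 0.954 (Pearson; genes are not independent replicates). Their counts differed by 51.0 to 119.42 times the variance of counting error. On the first principal component, with 31.3% of variance, the monocytes scored 95.5 to 161.8, pop4 -6.8 to 61.3 and the other adipose libraries -155.4 to -57.7. Within some populations the score also fell with background counts in olfactory and vomeronasal receptor genes. Monocyte CD replicates 1 and 6 (243 and 238 CPM) scored 96.7 and 95.5, and replicate 2 (85.3 CPM) 160.2. Pop2 scored -106.4 and -101.2 on the CD (370 and 387 CPM) and -143.9 and -155.4 on the HFD (548 and 781 CPM). In pop1 the order was mixed. The component therefore need not reflect cell population alone.

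**Figure D1:**
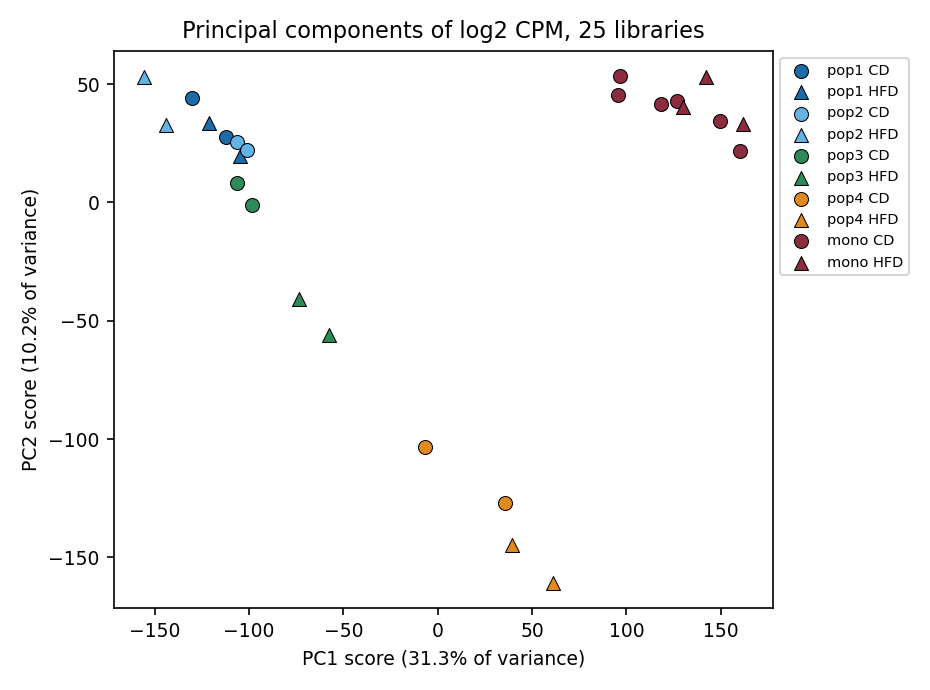
Scores of the 25 libraries on the first (31.3% of variance) and second (10.2%) principal components of log2 CPM. Each point is a library, colour gives the population and shape the diet (circles CD, triangles HFD).

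The first comparison asked how macrophages of adipose tissue differ from blood monocytes. Dab2 (chromosome 15, 6386748 to 6440709), an endocytic adaptor, was read at 1110 ± 395 CPM in adipose macrophages (n = 16) and 0.765 ± 0.401 in monocytes (n = 9), a log2 difference of 10.49 (SE 0.29, adjusted p = 2.98e-16). C1qa, a chain of complement C1q, was at 464 ± 184 against 0.265 ± 0.218 and the chemokine genes Cxcl12 and Ccl7 at 222 ± 134 against 0.124 ± 0.12 and 339 ± 152 against 0.21 ± 0.19. Kitl, the ligand of the receptor Kit, was at 319 ± 133 against 0.311 ± 0.241 and Car3 at 169 ± 102 against 0.0811 ± 0.105. Rhoc was at 59.4 ± 23.2 against 0.0415 ± 0.0624 and Fxyd2 at 222 ± 121 against 0.255 ± 0.414 (adjusted p of these 7 genes 1.17e-15 to 8.34e-10). Pdgfc (chromosome 3, 81036416 to 81214031), a platelet-derived growth factor gene, was read at 168 ± 122 CPM in adipose macrophages and 0.139 ± 0.192 in monocytes (log2 difference 9.72, SE 0.88, adjusted p = 2.55e-08). Monocytes had more Mmp8, a collagenase, at 714 ± 139 CPM against 1.43 ± 1.88 (log2 difference -9.29, SE 0.35). In total 3139 genes were higher and 3139 lower in adipose macrophages. With DESeq2 size factors the numbers were 3726 and 2522, and with upper-quartile factors 3576 and 2638.

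The resident macrophage list had 23 of its 25 tested genes higher in adipose macrophages and 1 lower (camera adjusted p = 8.54e-31). Folr2, a folate receptor, was read at 512 ± 302 CPM against 0.87 ± 1.85 (log2 difference 9.1, SE 0.68). Lyve1, a hyaluronan receptor, was at 490 ± 349 against 0.509 ± 0.335. Its call was lost without replicate 2 of pop4 HFD, a group with 0 to 0.246 CPM of Lyve1 that was then left with 1 library. The log2 level of such a group is poorly determined, so that fit does not bear on the size of the difference. Of 11 classical monocyte genes 10 were lower (camera adjusted p = 7.51e-26), among them Ly6c2 (-8.33, SE 0.41), a gene of the sort gate, and Chil3 (-8.3, SE 0.35). The non-classical monocyte list had 9 of 10 genes lower (8.1e-14), with Treml4 at -7.2 (SE 0.51). All 19 interferon-stimulated genes were lower (6.31e-15), and Irf7, a transcription factor of the interferon response, was read at 14.3 ± 16.6 CPM against 232 ± 56.7. The complement list had 8 of 15 higher and 2 lower (3.76e-09; 9 and 2 adjusted over the list alone). The growth factor list had 9 of 20 higher and 1 lower (0.00279; 10 and 2 adjusted over the list alone). It includes Igf1 at 1160 ± 525 CPM against 4.56 ± 6.21, whose call was lost in DESeq2, and Bmp2 at 71.5 ± 57.1 against 0.0551 ± 0.0654. The call of Bmp2 was lost without replicate 8 of pop4 CD, which left 1 library in that group. In pop4 Bmp2 averaged 0.465 ± 0.768 CPM, so its log2 level there is poorly determined. The lipid-associated macrophage list had 15 of 24 higher and 2 lower (1.46e-06), with Cd63, a tetraspanin of lysosomes, at 8.61 (SE 0.53). These 7 calls held with an estimated correlation between genes, at adjusted p 8.55e-07 to 0.0401.

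Markers of other cells also differed between the tissues. The adipocyte list had 8 of 10 genes higher in the adipose libraries (camera adjusted p = 0.0118; adjusted p = 0.185 with an estimated correlation), with Adipoq, the adiponectin gene, at 47.4 ± 48.6 CPM against 0.0818 ± 0.14. The stromal progenitor list had 10 of 11 higher and 1 lower (0.00202; adjusted p = 0.125 with an estimated correlation), with Dcn, a matrix proteoglycan gene, at 211 ± 230 CPM against 0.272 ± 0.289. All 8 red cell genes were lower in the adipose libraries (2.17e-08; adjusted p = 0.079 with an estimated correlation), as were 5 of 7 platelet genes (0.0316; adjusted p = 0.167 with an estimated correlation). The proliferation list had 11 of 20 higher and 1 lower (1.12e-04; 15 and 1 adjusted over the list alone), with an adjusted p = 0.079 with an estimated correlation. Antigen presentation had 6 of 15 higher and 3 lower (0.00294), iron and heme handling 8 of 14 higher and 1 lower (0.013; 9 and 1 adjusted over the list alone), and dendritic cell 2 of 15 higher and 7 lower (0.00202). With an estimated correlation their adjusted p were 0.148, 0.0893 and 0.0851. For adipocyte genes, 8 were higher and 1 lower adjusted over the list alone. Where no count adjusted over the list alone is given, here and in the other comparisons, it equalled that over all genes.

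The remaining 15 lists passed no threshold. Their camera adjusted p were 0.11 for sort markers, 0.971 for inflammatory cytokines, 0.971 for sterol and fatty acid synthesis, 0.11 for oxidative phosphorylation, 0.147 for lysosome, 0.809 for immediate early and heat shock, and 0.879 for peritoneal macrophage. They were 0.699 for T cell, 0.45 for B cell, 0.449 for NK cell, 0.916 for neutrophil, 0.663 for eosinophil and mast cell, 0.189 for endothelial, 0.246 for mesothelial and 0.476 for the sex chromosome check. For sterol synthesis the median (0.24) and mean (0.22) log2 differences had the other sign than the test. For immediate early genes the median was -0.11 and the mean 0.49, and for the sex chromosome check -0.08 and 0.01. Among the genes of the gates, Timd4 was at 189 ± 238 CPM against 0.247 ± 0.249 (adjusted p = 0.00415). That call was lost without replicate 3 of pop4 HFD, which left a group of 1 library with 0 counts, whose log2 level is not determined. H2-Eb1 differed by 3.99 (SE 0.3), H2-Ab1 by 2.19 (SE 0.16), H2-Aa by 1.68 (SE 0.12) and Cd74 by 1.03 (SE 0.08). Csf1r, which encodes CD115, was read at 500 ± 147 CPM in adipose macrophages and 455 ± 43.1 in monocytes (adjusted p = 0.685), and the adjusted p of Itgax was 0.819. Lower in adipose macrophages, Trem3, Ly6i, Ms4a4b, Bmx and Cd177 were at 0.184 ± 0.18 to 3.84 ± 9.9 CPM there and at 101 ± 53.8 to 246 ± 50.8 in monocytes (adjusted p 3.47e-12 to 1.7e-08). DESeq2 size factors moved the median of all genes by 0.15 and upper-quartile factors by 0.12. Counts in olfactory and vomeronasal receptor genes, a measure of background, were 80.1 to 781 CPM in adipose and 85.3 to 243 in monocyte libraries, and with this measure as a covariate the number of genes called was 1481.

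**Figure D2:**
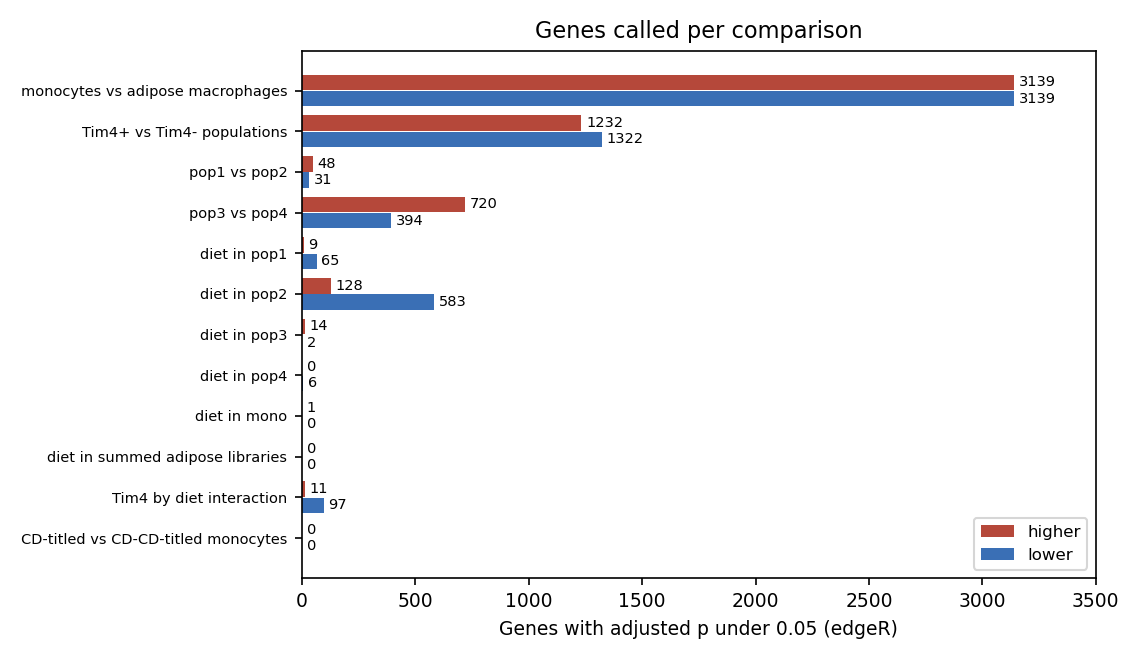
Genes with an adjusted p under 0.05 in each comparison, higher (red) and lower (blue) in adipose macrophages, in the first-named group, on the HFD, or in the CD-CD titles. For the interaction, higher means a more positive log2 difference of HFD against CD in Tim4+ than in Tim4- populations, whatever its size.

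Tim4+ populations (pop1 and pop2, n = 8) were compared with Tim4- populations (pop3 and pop4, n = 8). Timd4 itself (chromosome 11, 46810799 to 46844333), a receptor for phosphatidylserine, was read at 376 ± 206 CPM against 3 ± 5.12 (log2 difference 8.28, SE 0.72, adjusted p = 1.37e-07). Pdgfc was higher in Tim4+ populations, at 268 ± 63.2 CPM against 69.3 ± 73.5 (log2 difference 2.92, SE 0.54, adjusted p = 8.54e-04). The lectin gene Cd209f was at 577 ± 58.9 against 153 ± 165 (4.88, SE 0.3) and Lyve1 at 760 ± 177 against 220 ± 251 (5.02, SE 0.34). The contrast weighs pop4, where Cd209f and Lyve1 averaged 4.1 ± 4.53 and 5.3 ± 7.49 CPM, like pop3, so their fitted differences exceed those of the means. Tim4- populations had more Ccr2 (chromosome 9, 124102183 to 124109140), a chemokine receptor of monocytes, at 1350 ± 270 CPM against 189 ± 196 (-4.07, SE 0.4), and more Mmp12, a macrophage elastase, at 474 ± 524 against 1.15 ± 0.806 (-7.08, SE 0.89). Mmp12 averaged 49.9 ± 89 CPM in pop3 and 899 ± 392 in pop4. In total 1232 genes were higher and 1322 lower in Tim4+ populations. With DESeq2 size factors, which moved the median of all genes by 0.12, the numbers were 1625 and 1074.

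The resident macrophage list had 21 of 25 genes higher in Tim4+ populations (22 adjusted over the list alone, camera adjusted p = 2.59e-45). Its summed level averaged 18200 to 21200 CPM in the Tim4+ groups. It averaged 16600 (CD) and 13000 (HFD) in pop3 and 4220 and 3720 in pop4, so much of the difference lay in pop4. The peritoneal macrophage list had 6 of 9 higher (8 adjusted over the list alone; 4.03e-05) and iron and heme handling 6 of 14 (0.00334). The peritoneal list summed to 2000 ± 77.8 CPM in pop1 CD and 285 ± 126 in pop1 HFD, but to 60.9 to 110 in the libraries of pop2, pop3 and pop4, so pop1 alone carried it. Slc40a1, the iron exporter ferroportin, was at 250 ± 163 CPM against 109 ± 161 (adjusted p = 8.31e-04). Of the Tim4- populations, pop3 had 211 ± 180 CPM of it and pop4 7.43 ± 14.5. The proliferation list had 14 of 20 genes lower (16 adjusted over the list alone; 1.54e-15), with Rrm2, a subunit of ribonucleotide reductase, at 0.855 ± 0.607 CPM against 74 ± 34.4, and Ube2c at 1.27 ± 2.25 against 106 ± 65.1. Antigen presentation had 9 of 15 lower and 1 higher (10 and 1 adjusted over the list alone; 1.01e-06). There, H2-DMb1 differed by -1.45 (SE 0.14), H2-Ab1 by -0.98 (SE 0.17), H2-Aa by -0.7 (SE 0.12), H2-Eb1 by -1.04 (SE 0.27) and Cd74 by -0.67 (SE 0.08). The antigen presentation sum averaged 3280 (CD) and 3120 CPM (HFD) in pop1, which was sorted for low MHCII. It averaged 5970 to 7540 in the groups of pop2, pop3 and pop4, so much of the difference lay in pop1 and follows its gate. H2-Aa was at 1420 ± 228 CPM in pop2 and 1420 ± 182 in Tim4- populations, whereas H2-DMb1 was lower in pop2 too (196 ± 41.8 against 349 ± 71.1). Classical monocyte genes were lower in 6 of 11 cases (7 adjusted over the list alone; 4.27e-07) and sterol synthesis genes in 4 of 21 (9 adjusted over the list alone; 1.96e-04), with Cyp51 at -2.57 (SE 0.43). These 7 calls held with an estimated correlation, at adjusted p 2.25e-09 to 0.043. Other calls were lost with it: complement (6 higher, 1 lower; 6 and 2 adjusted over the list alone; 9.4e-04; adjusted p = 0.0538 with an estimated correlation) and lipid-associated macrophage (3 higher, 8 lower; 3 and 9 adjusted over the list alone; 0.00334; then 0.183). So was interferon-stimulated (4 higher; 8 higher and 1 lower adjusted over the list alone; 0.0104; adjusted p = 0.322 with an estimated correlation). The same held for neutrophil (2 of 8 higher; 0.0146; adjusted p = 0.12 with an estimated correlation) and red cell (6 of 8 higher; 8 adjusted over the list alone; 0.00362; then 0.357).

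Other genes higher in Tim4+ populations were C6, a complement component, at 81.5 ± 44 CPM against 3.11 ± 7.19, Fgf9 at 36.5 ± 22.4 against 0.885 ± 1.26 and Cd209g at 404 ± 43.1 against 106 ± 123. Optn was at 33.1 ± 16.7 against 1.26 ± 1.68 and Bmp2, a bone morphogenetic protein gene, at 109 ± 45.2 against 33.5 ± 40.5 (adjusted p 9.69e-08 to 5.1e-04). Cd5l was at 68.6 ± 71.5 CPM against 0.198 ± 0.218, Adgrg1 at 58.6 ± 34.6 against 3.27 ± 5.85, and the cytokine gene Il10 at 42.4 ± 26.7 against 0.386 ± 0.626 (adjusted p 4.67e-06 to 6.38e-05). Itgax, which encodes CD11c, was lower at 1.23 ± 0.852 against 103 ± 89 CPM (-5.49, SE 0.76). It averaged 20.1 ± 18.4 CPM in pop3 and 185 ± 5.06 in pop4. Gdf3 was lower as well, at 1.51 ± 1.4 against 54.6 ± 38.1 (-5.35, SE 0.81). Klrk1 was at 0.355 ± 0.299 against 126 ± 125, Sept6 at 0.737 ± 0.567 against 87.5 ± 51.8 and the cytokine gene Il1b at 5.17 ± 13.8 against 97.8 ± 99.3. The mitosis genes Pbk and Cdca3 were at 1.26 ± 1.51 against 68.9 ± 37.7 and 0.749 ± 0.874 against 55.1 ± 31.9. Tcf19, Bcl2a1d and Sirpb1b were at 0.549 ± 0.973 to 1.59 ± 2.19 CPM against 24.9 ± 26.3 to 33.1 ± 13.8. Csf1r was higher at 0.66 (SE 0.08), and Ly6c2 was at 1.05 ± 0.663 against 5.04 ± 7.93 CPM (adjusted p = 0.0574). All named genes of this comparison that passed stayed past the threshold whichever library was left out. The number of genes called was 419 with the background covariate, 353 in the CD groups alone and 1378 without the pair of pop2 HFD libraries; Pdgfc was not called with the covariate or in the CD groups alone.

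**Figure D3:**
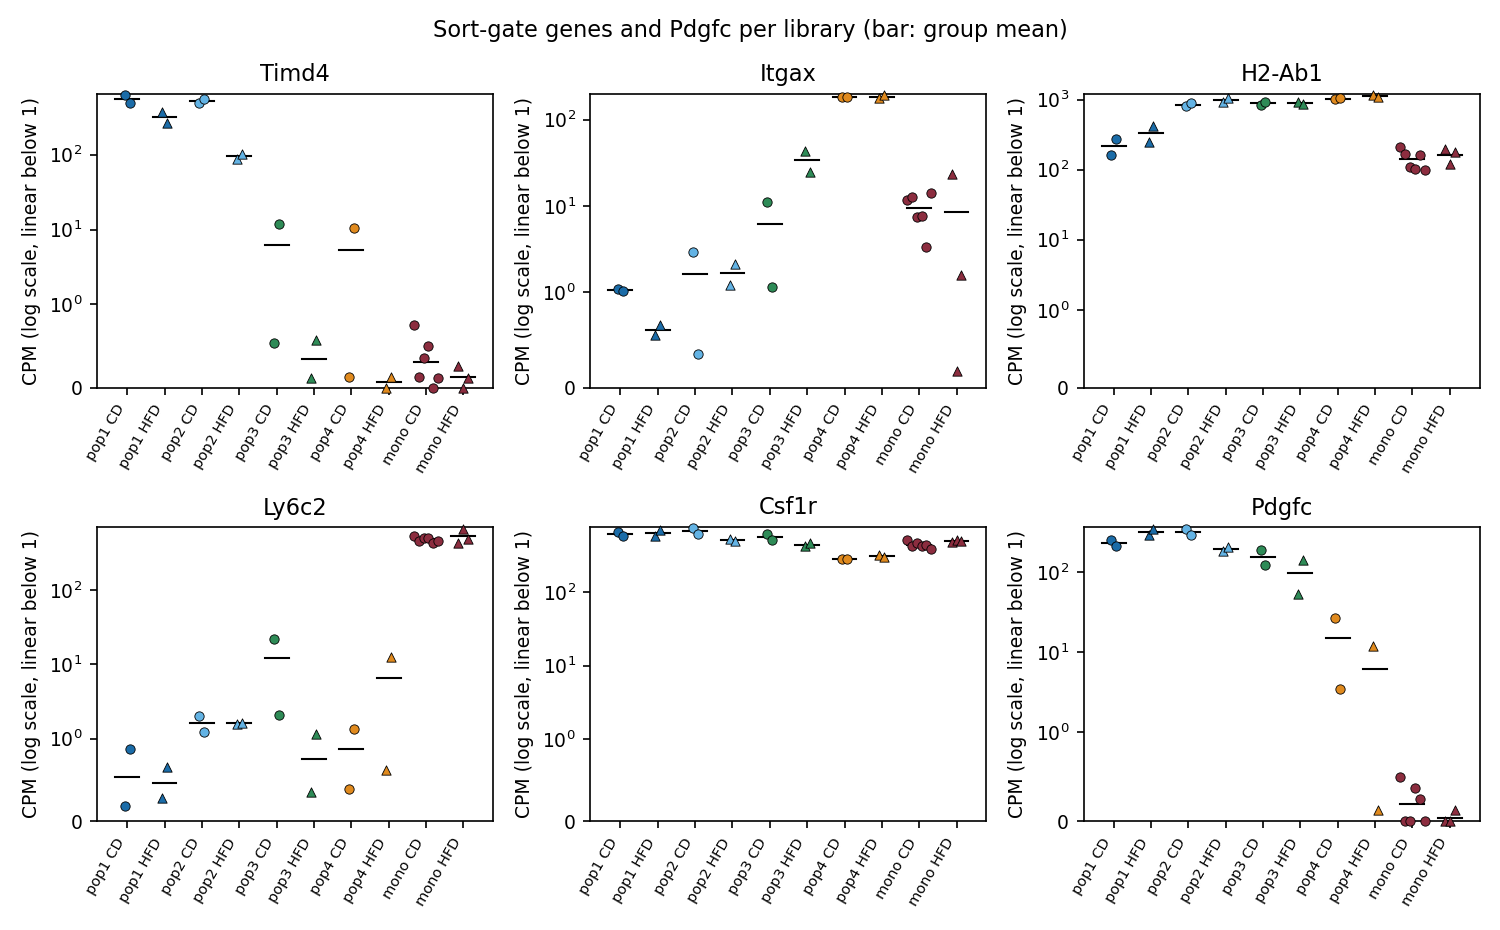
CPM of 5 genes of the sort gates and of Pdgfc in each library, with the group mean as a bar, on a log scale that is linear below 1 CPM. Pdgfc averaged 275 ± 55.5 CPM in pop1, 260 ± 77.9 in pop2, 128 ± 57.4 in pop3 and 10.6 ± 11.9 in pop4 (SD, n = 4), and 0.139 ± 0.192 in monocytes (n = 9).

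The Tim4+ populations were then compared with each other (pop1 against pop2, n = 4 each). Genes of class II antigen presentation were lower in pop1, the MHCII low gate: H2-Ab1 (chromosome 17, 34263227 to 34269418) was read at 276 ± 105 CPM against 917 ± 105 (log2 difference -1.76, SE 0.24, adjusted p = 4.19e-04). H2-Aa was at 540 ± 109 against 1420 ± 228 (-1.39, SE 0.17) and Cd74, the invariant chain, at 541 ± 43.9 against 1260 ± 112 (-1.21, SE 0.12). Genes of peritoneal macrophages were higher in pop1. The lipoxygenase gene Alox15 (chromosome 11, 70344147 to 70352031) was at 162 ± 144 CPM against 0.297 ± 0.244 (8.38, SE 1.31, adjusted p = 0.00215), the coagulation factor gene F5 at 133 ± 125 against 1.72 ± 0.533 (5.63, SE 0.74) and Prg4, the lubricin gene, at 427 ± 303 against 73.8 ± 18.1 (2.21, SE 0.26). Fibronectin, Fn1, was also higher (2.65, SE 0.3), and Ccr2 was lower, at 28.3 ± 45.8 CPM against 350 ± 137 (-4.17, SE 0.57). Pdgfc did not differ between them by more than its error (0.11, SE 0.71, adjusted p = 0.992).

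In pop1, 48 genes were higher and 31 lower than in pop2. The peritoneal macrophage list had 4 of 9 genes higher (6 adjusted over the list alone; camera adjusted p = 2.61e-20), antigen presentation 5 of 15 lower (7 adjusted over the list alone; 5.99e-10) and sort markers 4 of 13 lower (6 adjusted over the list alone; 7.17e-10). With an estimated correlation their adjusted p were 3.78e-05, 0.00944 and 0.00909, and both of the last lists hold H2-Aa, H2-Ab1, H2-Eb1 and Cd74. No red cell gene passed over all genes, 5 of 8 were lower when adjusted over the list alone, and the list had an adjusted p = 2.34e-07, or an adjusted p = 0.157 with an estimated correlation. Summed red cell counts ranged from 1.46 to 637 CPM in pop1 and from 21.1 to 1010 in pop2. Nmrk1 (4.86, SE 0.64), Grk3 (-3.96, SE 0.48), Evi2b (-2.28, SE 0.33) and H2-DMb1 (-1.28, SE 0.19) also differed whichever library was left out. Fosb (32.6 ± 14.8 against 0.54 ± 0.627 CPM, adjusted p = 0.00829), Tgfb2 (6.04), Itga6 (5.21), Selp (5.13), Padi4 (4.45), AI504432 (-4.99), Rasgrp1 (-4.38), Pak4 (-3.6), Slc35a2 (-2.55), Fam58b (-2.32) and H2-Eb1 (-1.98, SE 0.39) passed with all libraries. Leaving out 1 library raised the adjusted p of each past the threshold in 1 to 7 of 8 cases, to 0.0577 to 0.192 at most. The adjusted p was 0.765 for Timd4, 0.848 for Itgax, 0.935 for Csf1r and 0.551 for Ly6c2. Without replicate 2 of pop2 HFD 215 genes were called, and a fit of the pop1 and pop2 libraries alone called 6.

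The Tim4- populations were compared in the same way (pop3 against pop4, n = 4 each). Resident macrophage genes were higher in pop3: Lyve1 (chromosome 7, 110850607 to 110862953) was read at 435 ± 155 CPM against 5.3 ± 7.49 (log2 difference 8.48, SE 0.56, adjusted p = 3.65e-09). Cd209f was at 303 ± 64.9 against 4.1 ± 4.53 (7.87, SE 0.49) and Cd209g at 212 ± 73.4 against 0.684 ± 1.29 (9.34, SE 0.8). The apolipoprotein gene Apoe was at 708 ± 40 against 211 ± 74.4 (1.76, SE 0.22) and Bmp2 at 66.5 ± 30.4 against 0.465 ± 0.768 (7.52, SE 0.89). Pdgfc was higher in pop3, at 128 ± 57.4 CPM against 10.6 ± 11.9 (3.69, SE 0.79, adjusted p = 0.00776, and 0.0491 at most with 1 library left out). Pop4 had more Itgax (chromosome 7, 128129568 to 128150657), at 185 ± 5.06 CPM against 20.1 ± 18.4 (-3.67, SE 0.97, adjusted p = 0.0271), a call lost in 7 of 8 cases with 1 library left out (0.116 at most). It also had more Mmp12, at 899 ± 392 against 49.9 ± 89 (-5.72, SE 1.11), and Ccl17, a chemokine gene, at 82.4 ± 33.7 against 0.191 ± 0.202 (-8.75, SE 1.64).

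In pop3, 720 genes were higher and 394 lower than in pop4. With DESeq2 size factors, which moved the median of all genes by 0.13, these were 882 and 298. The resident macrophage list had 21 of 25 higher (22 adjusted over the list alone; camera adjusted p = 8.71e-58; adjusted p = 2.41e-09 with an estimated correlation), and complement 4 of 15 (5 adjusted over the list alone; 1.42e-04; then 0.049). No sterol synthesis gene passed, yet the list as a whole was lower in pop3 (0.00111; adjusted p = 0.0126 with an estimated correlation). Calls lost with an estimated correlation were proliferation (1 of 20 lower; 7.54e-04; adjusted p = 0.109 with an estimated correlation) and oxidative phosphorylation (3 of 20 lower; 0.00123; then 0.109). So were neutrophil (2 of 8 higher; 3 adjusted over the list alone; 0.00433; adjusted p = 0.0818 with an estimated correlation) and iron and heme handling (5 higher, 1 lower; 6 and 1 adjusted over the list alone; 0.0263; then 0.13). The same held for antigen presentation (2 of 15 lower; 0.032; adjusted p = 0.333 with an estimated correlation), dendritic cell (1 higher, 3 lower; 2 and 6 adjusted over the list alone; 0.032; then 0.227) and red cell (2 of 8 higher; 4 adjusted over the list alone; 0.038; then 0.489). Btnl2 was higher in pop3, at 61.7 ± 32.4 CPM against 0.129 ± 0.185, as was Chp2 at 38.5 ± 24.2 against 0.0962 ± 0.124. Gpr18 was lower at 0.284 ± 0.251 against 36.5 ± 25.2, as were the lectin-like receptor genes Klrb1a at 1.08 ± 1.15 against 119 ± 23.3 and Klrb1b at 0.507 ± 0.0519 against 60.6 ± 48.9 (adjusted p of Klrb1b 4.16e-04). NK cell genes summed to 14.1 ± 14.3 (CD) and 8.83 ± 8.3 CPM (HFD) in pop3 and 116 ± 4.24 and 65.6 ± 3.61 in pop4. Stromal progenitor genes (1090 ± 754 and 570 ± 496 in pop3, 292 ± 124 and 328 ± 117 in pop4) and platelet genes (164 ± 32.5 and 73.3 ± 56.1, 12.4 ± 5.37 and 25.1 ± 21.7) had higher sums in pop3. None of these 3 passed as a list (camera adjusted p 0.105 to 0.688). Slc40a1 was at 211 ± 180 against 7.43 ± 14.5 CPM, and Aspa, Hsf3 and Tfec at 30.8 ± 32.3 to 56.2 ± 50.5 against 0.0327 ± 0.0653 to 0.34 ± 0.679 (adjusted p 4.14e-04 to 0.00315). Fabp7 was lower in pop3, at 0.0285 ± 0.0569 against 22.2 ± 19.7 CPM (adjusted p = 0.00257). Ppic, higher in pop3, and Klri1, Gbp8 and Cd200r3, lower, passed with all libraries (adjusted p 0.00958 to 0.0282) but not in 3 to 8 of the 8 cases with 1 library left out (0.0773 to 0.121 at most).

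Csf1r was higher in pop3 (0.76, SE 0.12, adjusted p = 4.38e-04), and the adjusted p was 0.932 for H2-Aa, 0.485 for H2-Ab1, 0.951 for H2-Eb1, 0.167 for Cd74, 0.535 for Timd4 and 0.795 for Ly6c2. Background counts were 198 to 685 CPM in pop3 and 80.1 to 205 in pop4, and with this covariate 145 genes were called, Pdgfc, Itgax, Csf1r, Mmp12 and Ccl17 not among them. The number was 635 without replicate 8 of pop3 CD, 631 without replicate 2 of pop3 HFD, 605 and 473 without replicates 7 and 8 of pop4 CD, and 379 and 468 without replicates 2 and 3 of pop4 HFD.

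**Figure D4:**
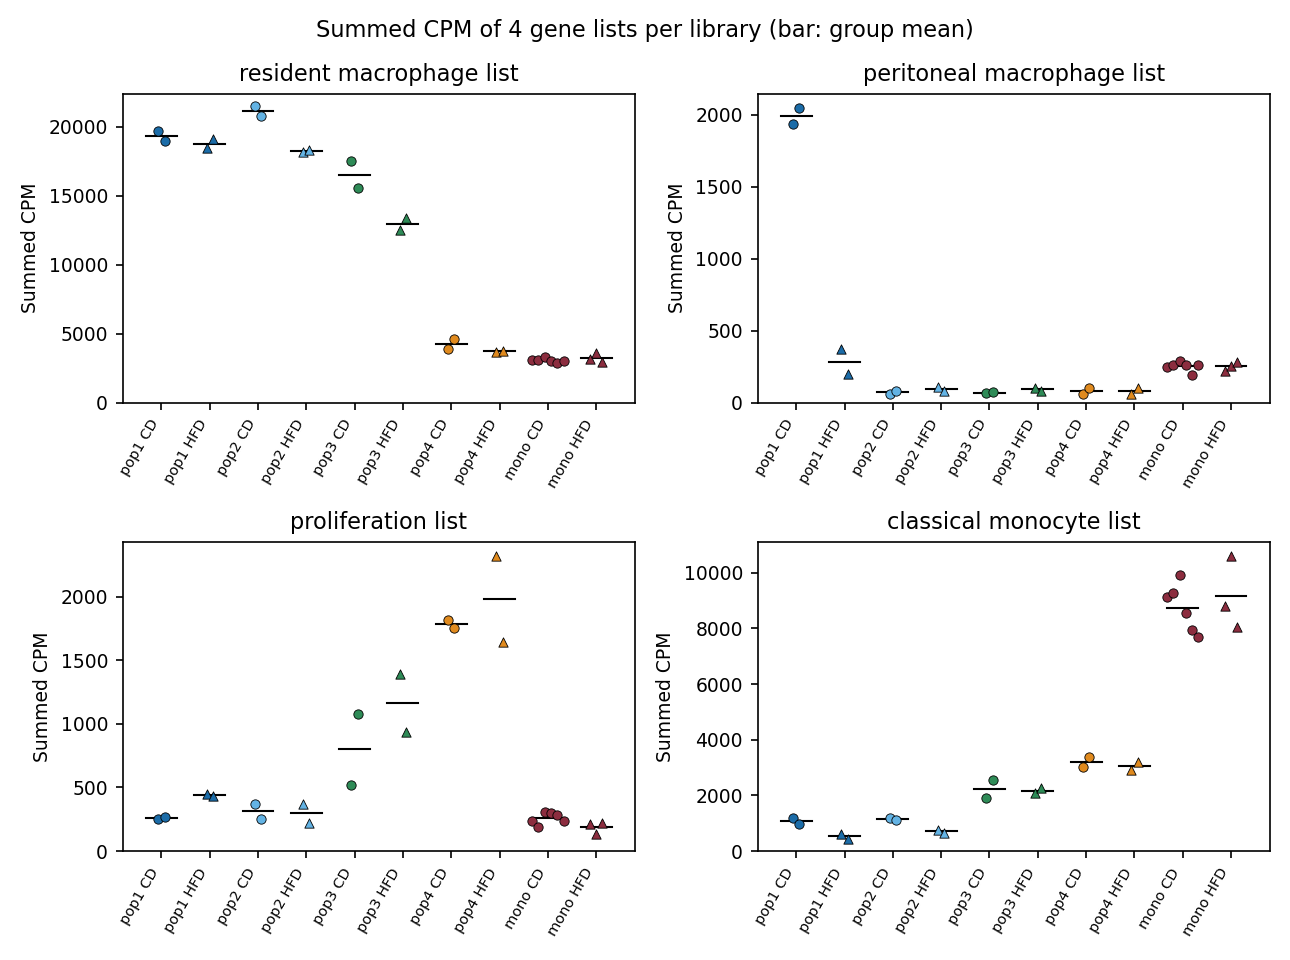
Summed CPM of the genes of 4 lists in each library, with the group mean as a bar (circles CD, triangles HFD). The resident macrophage sum lay between 3680 and 4590 in the pop4 libraries and between 12500 and 21500 in the other adipose libraries.

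The diets were compared within each population, HFD against CD, to ask how a diet with more fat changed each kind of cell (in adipose tissue every CD library has the title CD-CD). In pop1 (n = 2 each) the peritoneal macrophage genes were lower on the HFD: their summed level was 2000 ± 77.8 CPM on the CD and 285 ± 126 on the HFD. Gata6 (chromosome 18, 11052510 to 11085635), a transcription factor of peritoneal macrophages, was at 0.15 ± 0.0175 CPM on the HFD against 46.9 ± 2.12 (adjusted p = 0.0458). Prg4 was at 166 ± 55.7 against 688 ± 31.3 (log2 difference -2.05, SE 0.37, adjusted p = 0.0122) and the adhesion gene Icam2 at 0.62 ± 0.877 against 116 ± 127. Serpinb10, a serine protease inhibitor gene, was at 0.162 ± 0.23 against 74 ± 3.3 CPM (-8.78, SE 0.98, adjusted p = 2.2e-04). Higher on the HFD were Gmnn, an inhibitor of DNA replication (4.46, SE 0.86), the kinase gene Braf (3.28, SE 0.53), Ralgapa1 (2.95, SE 0.48), Tnrc6b (1.94, SE 0.41), Prrc2c (1.63, SE 0.35), Macf1 (1.45, SE 0.26), Arid4a (1.25, SE 0.21) and Tpr (1.12, SE 0.19).

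In pop1, 9 genes were higher and 65 lower on the HFD. The peritoneal macrophage list had 3 of 9 genes lower (6 adjusted over the list alone; camera adjusted p = 4.02e-11; adjusted p = 2.54e-04 with an estimated correlation). The classical monocyte list had 1 of 11 lower (4 lower and 1 higher adjusted over the list alone; 0.0173; adjusted p = 0.0582 with an estimated correlation), that gene being Fn1 (-1.83, SE 0.41). No red cell gene passed over all genes, 5 of 8 were higher adjusted over the list alone, and the list had an adjusted p = 0.0337, or an adjusted p = 0.901 with an estimated correlation. Also lower were Wnt2 at 0.0689 ± 0.0974 CPM against 25.8 ± 14.3, the chemokine gene Ccl11 at 0.394 ± 0.362 against 92.9 ± 40.4, Fabp5 at 0.288 ± 0.177 against 21.3 ± 6.75 and Rgs1 at 0.426 ± 0.372 against 22.1 ± 23.4. Cyp2r1 was at 30 ± 6.58 CPM on the CD with no counts on the HFD (adjusted p = 0.0499). Pdgfc was at 317 ± 38.1 against 234 ± 29.8 CPM (adjusted p = 0.939) and Timd4 at 317 ± 76.3 against 560 ± 92.5 (adjusted p = 0.842). Of these genes Serpinb10 alone passed whichever library was left out (0.0031 at most). Gata6, Wnt2, Ccl11, Fabp5, Cyp2r1, Tnrc6b and Prrc2c were lost whichever of the 4 libraries was left out (0.201 to 0.344 at most) and the others in 1 to 3 cases (0.0825 to 0.411 at most). The number of genes called was 27 and 26 without replicates 7 and 8 of CD, 112 and 25 without replicates 2 and 3 of HFD, 0 in a fit of the pop1 libraries alone, 2 in a fit of the adipose libraries and 736 in DESeq2. Background counts were 638 to 687 CPM on the CD and 267 to 293 on the HFD, and with this covariate 33 genes were called. Serpinb10, Ccl11, Braf and Arid4a were among them and the other named genes were not (Prg4 then -1.87, adjusted p = 0.092). Stromal progenitor genes (171 ± 59.4 against 530 ± 413 CPM) and T cell genes (12.7 ± 6.32 against 54.8 ± 34.9) had lower sums on the HFD as well, without passing as lists (camera adjusted p = 0.648 each).

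In pop2 (n = 2 each) 128 genes were higher and 583 lower on the HFD. The balance depends on scaling and test: DESeq2 size factors gave 162 and 429, upper-quartile factors 160 and 418, and the DESeq2 test 880 and 1035. Over all genes tested the median log2 difference was 0.3, opposite to the direction of most calls. The costimulatory ligand gene Cd86 was at 112 ± 40.6 CPM on the HFD against 526 ± 48.7 (log2 difference -2.23, SE 0.36, adjusted p = 0.00101). Fn1 (chromosome 1, 71585473 to 71653234) was at 21.5 ± 10.9 against 145 ± 124 (-2.75, SE 0.43, adjusted p = 7.4e-04). Gin1 was at 0.496 ± 0.701 against 104 ± 89.1 and Tatdn1 at 0.549 ± 0.215 against 74.1 ± 36.6, and these 4 genes passed whichever library was left out (0.0128 to 0.0331 at most). The classical monocyte list had 2 of 11 genes lower (3 adjusted over the list alone; camera adjusted p = 0.0409; adjusted p = 0.129 with an estimated correlation), among them Fn1. Markers of other cells moved both ways, with the summed T cell list at 17 ± 0.0707 CPM on the HFD against 122 ± 39.4 and the platelet list at 9.52 ± 3.37 against 78.8 ± 39.9. Red cell genes were at 838 ± 244 against 465 ± 628 and NK cell genes at 9.38 ± 4.84 against 3.19 ± 2.64, and none of these passed as a list (camera adjusted p 0.367 to 0.95). Neutrophil genes summed to 121 ± 85.1 CPM on the HFD against 303 ± 70.7. Timd4 was at 95.7 ± 9.62 CPM on the HFD against 530 ± 47.4 (-2.47, SE 1.04, adjusted p = 0.217) and Pdgfc at 196 ± 14.1 against 324 ± 38.8 (adjusted p = 0.751).

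Genes higher on the HFD in pop2 were Cyb561d1, Dus2, Ccdc85b, Oas1b, Tomm40, a gene of mitochondrial protein import, and Cadm1, with 0.726 ± 0.534 to 1.16 ± 0.0837 CPM on the CD and log2 differences of 4.88 to 5.9, and Zfp771, at 22.5 ± 13.3 CPM with no counts on the CD. Lower were the platelet chemokine gene Ppbp, Armcx5, Lipt2, Zfp97, Gk and Ctla2a, at 0.117 ± 0.165 to 0.233 ± 0.33 CPM against 35.4 ± 32.7 to 71.6 ± 37. The adjusted p of these genes were 0.00281 to 0.0497, and with 1 library left out each was lost in 1 to 3 of 4 cases (0.0528 to 0.613 at most). DESeq2 size factors moved the median of all genes by 0.15 and upper-quartile factors by 0.16. The number of genes called was 453 without replicate 8 of CD, 428 without replicate 3 of HFD, 445 with the background covariate, 249 in a fit of the adipose libraries, 0 in a fit of the pop2 libraries alone and 1915 in DESeq2.

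In pop3 (n = 2 each) 14 genes were higher and 2 lower on the HFD. Nmrk1, a kinase of nicotinamide riboside, was at 0.234 ± 0.17 CPM on the HFD against 45.3 ± 0.54 (log2 difference -7.5, SE 1.05, adjusted p = 0.00752, and 0.0441 at most with 1 library left out). The phospholipase gene Plcg2 was at 158 ± 24 against 26.2 ± 12.8 (2.59, SE 0.38, adjusted p = 0.00905; 0.114 without replicate 8 of CD). The lysosomal protease gene Ctsz was at 349 ± 40 against 130 ± 7.7 (1.42, SE 0.27) and the ribosomal protein gene Rpl5 at 171 ± 93.5 against 23.9 ± 4.38 (2.83, SE 0.5). Snrnp25 (6.61), Cd244 (5.42), Ndufa10 (4.17), Mea1 (3.28) and Napsa (2.9) were also higher and Fopnl (-1.49) lower, and with Ctsz and Rpl5 each was lost in 2 or 3 of 4 cases with 1 library left out (0.0966 to 0.351 at most). No member of the interferon-stimulated and immediate early lists passed over all genes, 3 were lower and 1 higher adjusted over the list alone, and the lists had camera adjusted p = 0.0259 (lower) and 0.0317 (higher), each with an adjusted p = 0.683 with an estimated correlation. Summed markers of other cells were lower on the HFD for eosinophils and mast cells (6.38 ± 0.643 against 62.8 ± 46.7 CPM), T cells (49 ± 6.08 against 110 ± 41.2), neutrophils (98.8 ± 48.4 against 232 ± 50.9), platelets (73.3 ± 56.1 against 164 ± 32.5) and stromal progenitors (570 ± 496 against 1090 ± 754). They were higher for red cells (248 ± 345 against 78.7 ± 65.5), and none of these passed as a list (camera adjusted p 0.0987 to 0.966). Pdgfc was at 98.6 ± 63.8 CPM against 157 ± 48.5 (adjusted p = 0.858). With upper-quartile factors, which moved the median of all genes by -0.19, 9 genes were higher and 3 lower. The number of genes called was 26 and 5 without replicates 7 and 8 of CD, 8 and 87 without replicates 2 and 3 of HFD, 1 with the background covariate, 0 in fits of the pop3 or of the adipose libraries alone and 717 in DESeq2.

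In pop4 (n = 2 each) no gene was higher and 6 were lower on the HFD. They include 4 genes of resident macrophages at low levels. Gas6 (chromosome 8, 13465374 to 13494535), which bridges dying cells to phagocytic receptors, was at 0.555 ± 0.261 CPM against 7.01 ± 1.54 (log2 difference -3.62, SE 0.44, adjusted p = 0.00102). Cd209f was at 0.185 ± 0.261 against 8.01 ± 0.489, Lyve1 at 0.123 ± 0.174 against 10.5 ± 7.81 (adjusted p = 0.00205 each) and the scavenger receptor gene Stab1 at 3.88 ± 1.48 against 23.4 ± 14.3 (-2.59, SE 0.45, adjusted p = 0.028). The resident macrophage list had 4 of 25 genes lower (7 adjusted over the list alone; camera adjusted p = 9.62e-08; adjusted p = 2.55e-04 with an estimated correlation). The other 2 genes were Btla, a receptor of lymphocytes and dendritic cells, at 0.0616 ± 0.0871 against 17.8 ± 19.1, and Dpysl3, at 20.8 ± 14.4 CPM on the CD with no counts on the HFD (adjusted p = 0.0132). Markers of other cells moved as well: the summed B cell list was at 99.8 ± 42.8 CPM on the HFD and 7.52 ± 4.91 on the CD. No member passed over all genes, and 2 of 6 were higher adjusted over the list alone (camera adjusted p = 3.06e-04; adjusted p = 0.0554 with an estimated correlation). The neutrophil list was lower, with 2 of 8 adjusted over the list alone (0.00292; adjusted p = 0.0743 with an estimated correlation), and so was the interferon-stimulated list, with 3 of 19 (0.00442; adjusted p = 0.513 with an estimated correlation). NK cell genes summed to 65.6 ± 3.61 CPM on the HFD and 116 ± 4.24 on the CD. Pdgfc was at 6.1 ± 8.45 against 15.1 ± 16.5 CPM (adjusted p = 0.956) and Itgax at 186 ± 7.94 against 184 ± 3.19.

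The calls of Gas6 (adjusted p = 0.0732) and of Btla, Cd209f and Lyve1 (0.128) were lost without replicate 3 of pop4 HFD, and those of Stab1 and Dpysl3 in 3 and 2 of 4 cases with 1 library left out (0.632 and 0.326 at most). The number of genes called was 2 without replicate 3 of HFD, 16 without replicate 7 of CD, 0 in a fit of the pop4 libraries alone and 130 in DESeq2.

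In monocytes 1 gene was called between the diets, C1qc (chromosome 4, 136889802 to 136892914), a chain of complement C1q. It was at 11.8 ± 10.3 CPM on the HFD (n = 3) and 0.556 ± 0.43 on the CD (n = 6; log2 difference 4.37, SE 0.55, adjusted p = 0.00156). Single libraries spanned 0.967 to 21.6 CPM on the HFD and 0.117 to 1.37 on the CD, so the diets overlapped. C1qc passed whichever library was left out (0.0461 at most). It did not pass in limma-voom, in a fit of the monocytes alone, against the controls of either title series alone, or with the title number as a block. The next smallest adjusted p were 0.0697 for Exosc9 (-1.91, SE 0.33), 0.209 for Pltp, 0.322 for Dip2b and 0.365 for Man1c1, and Ly6c2 was at 532 ± 125 against 483 ± 39.8 CPM. The resident macrophage list was higher on the HFD with no member past the threshold (camera adjusted p = 0.014; adjusted p = 0.0592 with an estimated correlation). At an unadjusted p under 0.05 there were 1169 genes, and DESeq2 called 140 and limma-voom 0. The number was 1 higher and 1 lower with upper-quartile factors, 2 and 4 in all without replicates 1 and 3 of CD, and 6 and 3 without replicates 1 and 2 of HFD.

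The counts of the 4 adipose populations were also summed per title number, to test diet over all of them (2 sums per diet). Depth was not equalized before summing, so each population weighed by its total counts. These were 4.73 to 5.86 M (CD) and 3.75 to 4.48 M (HFD) in pop2, and 5.07 to 5.57 M and 7.75 to 8.52 M in pop3. Differences between the sums can therefore reflect this mix of populations as well as diet. No gene passed in edgeR, with 2159 at an unadjusted p under 0.05, while DESeq2 called 492 higher and 352 lower. A mean diet contrast over the 16 libraries called 284 higher and 622 lower, and limma-voom with the title number as a random effect 95 and 341. The smallest adjusted p was 0.296, shared by many genes, and the 4 genes with the smallest unadjusted p follow. The purinergic receptor gene P2ry12 was at 121 ± 7.19 CPM on the HFD against 329 ± 16.3 (-1.48, SE 0.14) and Aoah at 86.9 ± 1.91 against 238 ± 16.4 (-1.49, SE 0.16). Gpr34 was at 234 ± 20.9 against 564 ± 60.9 (-1.31, SE 0.14) and the ribosomal RNA precursor Rn45s at 1040 ± 67.1 against 487 ± 56.6 (1.07, SE 0.11). Pdgfc was at 149 ± 22.1 against 170 ± 21.2 (-0.22, SE 0.19, adjusted p = 0.676). The peritoneal macrophage list was lower (0 of 9 over all genes and 8 adjusted over the list alone; camera adjusted p = 6.67e-14), as were complement (0 and 3 of 15; 6.01e-04) and lipid-associated macrophage (0 and 2 of 24; 0.028). Of the populations pop1 alone carried the peritoneal difference, since the list summed to 60.9 to 110 CPM in all other adipose libraries. Red cell (0.00239), immediate early (0.0157) and proliferation (0.0254) genes were higher as lists with no member past either threshold. All of these lists had an adjusted p = 0.8 with an estimated correlation. Upper-quartile factors moved the median of all genes by -0.13.

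The difference between the diet effects of Tim4+ and Tim4- populations was tested directly, and 108 genes passed, 11 with a higher and 97 with a lower diet effect in Tim4+ populations. Effects here are signed log2 differences, HFD minus CD. A higher effect in Tim4+ populations can therefore come from a fall in Tim4- populations, as in Kif21a (2.88 ± 5.29 CPM on the HFD against 31.1 ± 23.6 there). Gas6 was at 545 ± 67.8 CPM on the HFD and 336 ± 59.2 on the CD in Tim4+ populations and at 129 ± 150 and 108 ± 118 in Tim4- populations (n = 4 each), a difference of log2 effects of 2.35 (SE 0.37, adjusted p = 0.0053). This contrast weighs pop4, where Gas6 was at 0.555 ± 0.261 CPM on the HFD and 7.01 ± 1.54 on the CD, like pop3. The same limit holds for Cd209f (difference of log2 effects 2.66), which was lower on the HFD in Tim4+ (527 ± 26.3 against 628 ± 23.9 CPM) and in Tim4- populations (124 ± 144 against 183 ± 202). In pop4 it was at 0.185 ± 0.261 against 8.01 ± 0.489. Fn1 was at 104 ± 108 on the HFD and 405 ± 308 on the CD in Tim4+ populations and at 759 ± 318 and 721 ± 377 in Tim4- populations (-2.43, SE 0.4, adjusted p = 0.00794). Ctla2a was at 0.354 ± 0.363 and 26.4 ± 23.2 in Tim4+ and 22.1 ± 14.9 and 15.6 ± 18.9 in Tim4- populations (-8.01, SE 1.25, adjusted p = 0.0053). These 3 genes passed whichever library was left out (0.0229 to 0.026 at most). The resident macrophage list had 2 of 25 genes with a higher effect in Tim4+ populations (4 adjusted over the list alone; camera adjusted p = 0.00358). The classical monocyte list had 2 of 11 with a lower effect (6 adjusted over the list alone; 0.00157). Both had an adjusted p = 0.0179 with an estimated correlation. For Pdgfc the difference was 0.85 (SE 1.01, adjusted p = 0.769).

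The other genes named for this difference were Stab2 (6.34), Kif21a (6.3), B4gat1 (3.95), Cd209f, Rgs14 (2.23) and Tnrc6b (1.83), with a higher effect in Tim4+ populations. A lower effect was found for Nudt8 (-6.95), the lectin gene Clec4e (-6.58), Ccl11 (-6.4), Plac8 (-6.1), Fabp5 (-5.92) and Zc4h2 (-5.92). All of these genes, of either direction, were lost in 2 to 13 of 16 cases with 1 library left out (0.0894 to 0.187 at most). The fitted values of Stab2, Kif21a, Cd209f, Ctla2a, Nudt8, Ccl11, Plac8 and Fabp5 depend on the prior count, because an adipose group of each averaged under the floor. Cmtm8, at 0.0296 ± 0.0592 on the HFD and 12.4 ± 12.2 CPM on the CD in Tim4- populations, and Cyp2r1, at 0.715 ± 0.9 and 27.5 ± 20.7 in Tim4+ populations, each had a group without counts and were lost in 11 and 4 cases. The number of genes called was 184 without replicate 2 of pop1 HFD, 69 and 70 without replicates 7 and 8 of pop2 CD, and 321 without replicate 2 of pop2 HFD. It was 56 without replicate 8 of pop3 CD, 61 without replicate 3 of pop3 HFD, 20 and 174 without replicates 7 and 8 of pop4 CD, and 37 and 44 without replicates 2 and 3 of pop4 HFD. The number was 14 without the pair of pop2 HFD libraries and 17 with the background covariate. A fit of the adipose libraries alone called 2 genes with a higher and 0 with a lower effect in Tim4+ populations, and limma-voom 2 and 4. DESeq2 size factors and upper-quartile factors moved the median of all genes by 0.15 and 0.18.

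The control monocytes came in the title series CD and CD-CD (n = 3 each), which were compared as a check, with CD-CD minus CD as the difference. No gene passed in edgeR, with 876 at an unadjusted p under 0.05, and limma-voom called 0 and DESeq2 166 higher and 108 lower. The smallest adjusted p was 0.4, shared by many genes, and the 4 genes with the smallest unadjusted p were Impa1 at 343 ± 14.3 against 224 ± 20.2 CPM (0.65, SE 0.11), Glipr2 (0.65, SE 0.11), Rnf114 (0.89, SE 0.15) and Usp9x at 32.9 ± 10.5 against 125 ± 10.6 (-1.9, SE 0.31). Dendritic cell genes were higher as a list (4 of 12 adjusted over the list alone; camera adjusted p = 3.69e-04; adjusted p = 0.112 with an estimated correlation), as were T cell genes (0.00448; then 0.406). Lower as lists were non-classical monocyte (1 of 9 adjusted over the list alone; 9.67e-04; adjusted p = 0.112 with an estimated correlation) and classical monocyte (2 of 11 adjusted over the list alone; 0.00459; then 0.54). The same held for platelet (1 of 5 adjusted over the list alone; 0.00459; adjusted p = 0.223 with an estimated correlation), lipid-associated macrophage (0.00919; then 0.223) and complement (0.0177; then 0.318). Of the 30 lists, 8 had under 5 tested members here and were not tested.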

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

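The tests of explanations and of other splits of the libraries in this part were chosen after the results were seen, while the test of the difference between diet effects and the search for libraries far from their group were planned.

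The first pattern is the level of peritoneal macrophage genes in pop1 on the control diet, where the list summed to 2000 ± 77.8 CPM against 285 ± 126 on the high fat diet and 8 of its 9 genes lay above every other adipose library. Background reads as the cause are argued against: the 2 other adipose libraries with at least that background reached 84 CPM at most, a fraction of 0.043 of the lower pop1 control sum of 1940 CPM. A candidate explanation is that pop1 held peritoneal macrophages, which a gate on Tim4 and low MHCII would not remove, and fewer of them on the high fat diet. A smaller share of 1 cell type would leave its genes in 1 ratio. Of the 9 genes, 6 kept a share of their control level within 3-fold of the median share of 7.7%, too few to show this. Gata6 (-1.5%), Garnl3 (-2.8%) and Icam2 (-1.6%) fell below the pop2 level, lower than such a share would leave them. The negative signs are uncertain, since these genes were low in pop1 HFD (0.15, 1.08 and 0.62 CPM) and in pop2 (0.836, 1.6 and 2.46 CPM). Background was also higher in pop2 HFD (548 and 781 CPM) than in pop1 HFD (267 and 293 CPM). A response of pop1 to the diet stays open and untested, since diet and title series coincide in adipose tissue.

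The second pattern is the number of genes called for diet in pop2, 711 against 74 in pop1, 16 in pop3 and 6 in pop4. Lower depth of the pop2 HFD libraries is argued against, since with all libraries thinned to 3.75 M counts 706 genes were called in pop2 and 81, 19 and 6 in the others. Background reads as the whole cause are argued against by the covariate, which left 445 genes in pop2 and 33, 1 and 5 in the others. A loss of evenly expressed transcripts is argued against as well: of the 583 genes that were lower, 22.6% were steady in the 21 libraries outside pop2, against 32.1% of uncalled genes of the same level, a ratio of 0.705. A response of pop2 to the diet, other cells in the control sorts, both untested, and any other property of these libraries or of the title series stay open.

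The third pattern is the low level of resident macrophage genes in pop4 on the high fat diet. Background reads are argued against, since 5 of the 6 called genes passed with the covariate. A candidate explanation is that the pop4 control sort held some resident cells: 11 other genes had at least 30 CPM in each pop3 library and under 1% of their pop3 mean in both pop4 HFD libraries, and 7 of them, a fraction of 0.64, had at least 1% of it in the pop4 control libraries. Choosing genes for a low level on the high fat diet favours this outcome, and the reverse choice, of genes under 1% in both pop4 control libraries, gave 2 genes, 0 of them at 1% on the high fat diet. Timd4, which the pop4 gate excludes, was at 10.6 CPM in replicate 8 of pop4 CD and 0.131 in replicate 7, against 0 and 0.124 on the HFD (adjusted p = 0.365). Its level thus bears on carry-over in 1 control library, whereas Cd209f was at 7.67 CPM or more in both. The fraction of 0.64 lies between the bounds set for and against carry-over (0.8 and 0.2), and with so few genes carry-over and a response of pop4 to the diet cannot be told apart.

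Other splits of the same libraries into groups of the same sizes, in fits of the compared libraries, tested whether chance can be excluded. It can for monocytes against adipose macrophages (4178 genes, with 1 of 100 splits as large, the real one, highest other 1). The same holds for pop3 against pop4 (341 genes, 1 of 35, highest other 0). In both, this covers a random grouping of libraries only. The other splits mixed the compared populations, so they cannot tell cell population from background or, for monocytes, from tissue and handling. For Tim4 (390 genes, 1 of 100, highest other 2) chance can be excluded for a random grouping of libraries only. The splits mixed libraries of a population, so they cannot tell Tim4 from another grouping of the 4 populations. For the difference of diet effects 4 of 100 splits gave as many as the real 2 genes (highest other 4). That share is under 0.05, but another split gave more genes than the real one, so chance is not taken as excluded. These splits used the fit of the adipose libraries alone and do not cover the 108 genes of the fit of all libraries. Chance cannot be excluded for pop1 against pop2 either, with 3 genes and 2 of 35 splits as large. There the split with 23 genes set the CD libraries of both populations against the HFD libraries, which points to a structure of the samples by diet or title series. For diet in monocytes the real split called 0 genes (highest other 4). All 84 splits then necessarily gave as many, so they cannot decide the question. The 10 splits of the CD and CD-CD monocytes, all with 0 genes (highest other 0), are too few for a share under 0.05.

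The diet effect differed between Tim4+ and Tim4- populations in 108 genes in the fit of all libraries, in 2 in a fit of the adipose libraries alone and in 6 in limma-voom. The differences of log2 effects were 6.34 for Stab2, 6.3 for Kif21a, 3.95 for B4gat1, 2.66 for Cd209f, 2.35 for Gas6, 2.23 for Rgs14 and 1.83 for Tnrc6b. They were -8.01 for Ctla2a, -6.95 for Nudt8, -6.58 for Clec4e, -6.4 for Ccl11, -6.1 for Plac8, -5.92 for Fabp5, -5.92 for Zc4h2 and -2.43 for Fn1. The fitted differences of Cmtm8 (9) and Cyp2r1 (-8.83) depend on the prior count and measure no fold, because a group of each had no counts. Those of Stab2, Kif21a, Cd209f, Ctla2a, Nudt8, Ccl11, Plac8 and Fabp5 depend on it too, with an adipose group under the floor. In Cd209f and Gas6 the value rests on low levels in pop4, where carry-over stays open.

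Among the 6 control monocyte libraries, 6 of 70 values tested lay far from the others by Dixon's ratio, where chance gives about 1 in 20. The summed endothelial list was 32.7 CPM in replicate 6 against 8.36 in the next library. Fxyd2 was at 1.29 against 0.374 CPM in replicate 8, Folr2 at 5.79 against 0.502 in replicate 2, and Man1c1 at 112 against 64.2 in replicate 3. The values of Cxcl12 (0.352 against 0.127 in replicate 8) and Rhoc (0.125 in replicate 1 with no counts in the others) were at or under the floor of 3 counts, so their ratios do not set a library apart.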

How the results depend on the processing

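Contrasts of single diets and fits of the 16 adipose libraries, without the pair of pop2 HFD libraries and with the background covariate were added after the data were seen. The other settings were planned. Of 217 pairs of a named gene and a comparison 181 were past the threshold. With 1 library left out 2137 values kept their side of the threshold, 321 no longer passed and 9 newly passed. Under the 17 other settings 1867 kept their side, 391 no longer passed and 26 newly passed. None past the threshold changed sign, and signs of genes past no threshold were not counted. A group left with 1 library was assumed to vary like the other groups. Leaving out an adipose library also loosened the filter on low counts, to 18088 to 18841 genes tested against 16961. Changes in those fits are therefore not due to the missing library alone. The numbers of genes called that are not given here stayed within 1.5 times those of the report. Depth limits genes near the floor of 3 counts. Causes of these changes were not tested. Fits of fewer libraries have fewer residual degrees of freedom, whereas the contrasts of single diets used the fit of all 25 libraries.

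With 1 library left out, the number of genes called ranged from 4788 to 6296 for monocytes against adipose macrophages, 1773 to 2627 for Tim4, 55 to 215 for pop1 against pop2 and 379 to 827 for pop3 against pop4. For diet it ranged from 25 to 112 in pop1, 428 to 858 in pop2, 5 to 87 in pop3, 2 to 16 in pop4, 1 to 6 in monocytes and 0 to 0 in the summed libraries. It was 20 to 321 for the difference of diet effects and 0 to 0 for the title series.

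DESeq2 called 4092 genes for Tim4, 567 for pop1 against pop2, 2524 for pop3 against pop4, 736, 1915, 717 and 130 for diet in pop1 to pop4, 140 for diet in monocytes, 844 for the summed libraries, 540 for the difference of diet effects and 274 for the title series. Limma-voom called 33 for pop1 against pop2, 33, 99, 28 and 21 for diet in pop1 to pop4, 0 in monocytes and 6 for the difference of diet effects. A fit of only the groups compared called 6 for pop1 against pop2, 323 for pop3 against pop4, 0 for diet in each of pop1, pop2, pop3, pop4 and monocytes, and 2 for the difference of diet effects. The mean diet contrast over 16 libraries called 906 for diet in adipose tissue, and limma-voom with the title number as a random effect 436.

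The stricter filter gave 124 genes for diet in pop1, 45 in pop3 and 2 in monocytes, and no filter gave 36 in pop1. Upper-quartile factors gave 2 for diet in monocytes and 47 for the difference of diet effects, and DESeq2 size factors gave 58 for the latter. Control monocytes titled CD alone gave 0.

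The CD groups alone gave 3857 genes for monocytes against adipose macrophages, 353 for Tim4, 31 for pop1 against pop2 and 297 for pop3 against pop4. The HFD groups alone gave 3228 for monocytes against adipose macrophages and 146 for pop3 against pop4. The background covariate gave 1481 for monocytes against adipose macrophages, 419 for Tim4, 145 for pop3 against pop4, 33, 445 and 1 for diet in pop1, pop2 and pop3, and 17 for the difference of diet effects. The 16 adipose libraries alone gave 2, 249 and 0 for diet in pop1, pop2 and pop3. Without the pair of pop2 HFD libraries 1378 were called for Tim4 and 14 for the difference of diet effects.

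The labels do not say that numbers pair the libraries. With the title number as a block the numbers were 3378 (1525 higher, 1853 lower) for monocytes against adipose macrophages, 1472 (780 and 692) for Tim4, 8 for pop1 against pop2, 424 (331 and 93) for pop3 against pop4, 0 for diet in monocytes and 0 for the difference of diet effects. After group means were removed, 40 pairs of libraries with the same number and diet correlated across genes at -0.029 to 0.074 (median 5e-04), and 12 of the 16 adipose libraries correlated most with one of their own number. In groups of 2 the deviations mirror each other, so own and other number are equally likely by chance, and libraries of a group do not count separately.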
